A study of Homo sapiens and Mus musculus with 27 samples.

How the data were processed

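RNA was measured on 27 Affymetrix arrays that the labels place in 16 groups. The samples were primary human islets, the mouse pancreatic beta cell line MIN6, the human embryonic kidney line HEK293T in 2 experiments, mouse liver and primary mouse hepatocytes. About 5 µg of total RNA was used for each array, per the labels' protocols. The array types were HG-U133A_2 for the islets, MG_U74Av2 for MIN6 cells, HG-U133A for HEK293T cells and Mouse430_2 for liver and hepatocytes, per the file headers.

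The deposited values are 1 intensity per probe set and array on a linear scale, computed by the authors with the dChIP software, per the labels. The dChIP version, the normalization and the treatment of mismatch probes are not given in the sources used here. Some deposited intensities lie below 0 (up to 2.67% on an array), and up to 96 values per array are missing and were left missing. The scanner files name the chip type and, for some arrays, the chip lot and a comment, as text. Per the file headers the control and forskolin arrays of the HEK293T experiment with ACREB came from vector-transfected cells, which the sample labels do not say. The same headers give 1 lot for the 6 arrays of that experiment and 1 for the liver and hepatocyte arrays. The 2 untreated islet arrays came from 1 lot and the 2 forskolin arrays from another, all scanned on the same day. Lots of the MIN6 and HEK293T time course arrays are not given in the sources used here.

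Each table was analysed apart, since the tables come from different array types. Values under the 10th percentile of a table were set to it (an intensity of 97.1 for islets, 36.4 for MIN6, 24.5 for HEK293T and 124 for liver and hepatocytes), and log2 was then taken. Arrays were centred on their medians only where the medians of a comparison's arrays differed by more than 0.2 on the log2 scale. That was so for the HEK293T time course (a difference of 0.24) and for both HEK293T experiments together (0.41), and all other values were used as deposited. About 10% of the values of an array lay at the floor (6.92% to 14.8% over the arrays). For arrays, the number of arrays limits the precision.

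Probe sets were named from GEO's platform annotation. Of 22277 probe sets on the islet arrays, 19064 had 1 gene symbol, 1043 several and 2108 none. On the HEK293T arrays the numbers were 19065, 1043 and 2107 of 22283, on the MIN6 arrays 10833, 396 and 1193 of 12488, and on the liver and hepatocyte arrays 34945, 932 and 9160 of 45101. The remaining 62 to 68 probe sets of each array type were controls. Human symbols were updated through the gene identifiers of the RefSeq gene table of the GRCh38.p14 assembly, which matched 19052 islet and 19053 HEK293T probe sets. Mouse symbols were kept as annotated. Probe sets with several symbols or none named no gene. A gene was represented by its probe set with the highest mean over the arrays of the comparison, and genes below the 40th percentile of all probe sets were left out. In the replicated comparisons, the other probe sets of the named genes were fitted with all probe sets of 1 gene symbol and no filter, and their adjusted p is over all of these. For liver and hepatocytes the other probe sets of the named genes were not examined, so each ratio there rests on 1 probe set. Without the filter fewer genes passed in most comparisons. A probe set said not to pass there was thus held to a stricter test than the main one. Control probe sets, and in human samples XIST and Y-linked genes, were left out.

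Replicated comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The islets were fitted as 2 arrays against 2, and each of the 3 cell line experiments as 3 groups of 2. The 1 h effect of forskolin was also fitted over the 8 arrays of both HEK293T experiments, with the experiment as a block. Errors given as ± are standard errors of the fit. Liver and hepatocytes had 1 array per group and no test: a gene counted as changed at 2-fold or more when the higher value lay above the table's median. Where 1 of these values lay at the floor, the ratio is given as at least that large.

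For each of 28 gene lists of pathways and cell types, camera compared the moderated statistics of the list with those of all other genes at a preset correlation of 0.01, with adjustment over the lists of a comparison. Lists with fewer than 5 tested genes were not tested. The test was repeated with a correlation estimated from the data. That form uses the residual degrees of freedom of the fit, which are few here, so a list can hardly pass it after adjustment. A call lost there is thus not shown to rest on correlation between genes, and the preset form does not measure that correlation. Without replicates, the median of a list was placed among 10000 random lists of the same size matched on mean intensity. The effect of ACREB was measured over genes chosen on other arrays: for HEK293T the 50 rising genes with the smallest p at 1 h of the time course, since under 20 passed the threshold, and for MIN6 the union of the islet risers and the 50 rising genes with the smallest p in the pooled HEK293T arrays. The planned wording for MIN6 could also be read as the genes that passed the threshold in either source, and both readings are reported. Overlaps of rising genes were tested with Fisher's exact test and shared directions with the exact binomial test. Both treat genes as independent, so their p-values do not measure the spread between arrays.

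The genes named were set by rule: the 10 largest rises and 6 largest falls among genes that passed with groups that did not overlap (with fewer than 3 such genes, the 6 rising and 4 falling genes with the smallest p), 12 fixed CREB-responsive genes with 8 more in liver and hepatocytes, and up to 4 genes of each list that passed. Any gene named outside this rule is said to have been chosen after its value was seen. The sample groups, comparisons, tests, lists, naming rule and most alternatives were set before the data were examined. The alternatives were all probe sets, no intensity filter, a floor at the 20th percentile, quantile normalization, eBayes without the trend, the replicate number as a block, leaving out each replicate, and other choices of arrays in the fit.

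The steps were tested on simulated data made from the real means and spreads, with 200 genes changed. Over 20 draws the islet fit recovered on average 99.0% of 1.5-fold and 100% of 2-fold changes. For 2-fold changes the mean was 97.3% for forskolin and 97.4% for ACREB in MIN6 cells, 90.7% and 92.5% for the same comparisons in HEK293T cells, 79.9% at 1 h and 78.4% at 4 h of the time course, and 96.8% in the pooled HEK293T arrays. At 1.5-fold it fell to 16.3% at 1 h and 14.3% at 4 h of the time course. These shares hold for 200 changed genes with noise drawn independently for each gene. The real fits called as few as 2 genes. With fewer true changes the adjustment is stricter, so recovery may be lower than these shares. False calls made up a mean of 5.28% (pooled HEK293T) to 8.43% (islets) of the calls. Figures were drawn with matplotlib 3.10.9.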

Results

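Gene expression was measured to find genes that respond to cAMP, and to the transcription factor CREB, in different tissues. Forskolin, which activates adenylyl cyclase and raises cAMP, was applied to human islets for 1 h (2 arrays against 2 untreated), to MIN6 beta cells for 1 h, to HEK293T cells for 1 h or 4 h, and to hepatocytes for 1 h or 4 h. ACREB, a dominant negative form of CREB, was delivered to MIN6 cells by adenovirus, with a GFP virus as control, and to HEK293T cells by transfection. Livers of a mouse fasted for 20 h and of a mouse refed for 4 h after a 16 h fast were compared with 1 array each. The cell line groups held 2 arrays each, and the 3 hepatocyte times 1 each. The labels do not say that replicates came from separate cultures or donors, so p-values measure only the spread between these samples, which may be technical. Replicates correlated at 0.989 to 0.995 in islets, 0.973 to 0.989 in MIN6 cells and 0.955 to 0.976 in HEK293T cells. Array medians ran from an intensity of 88.8 to 118 for HEK293T, 189 to 202 for MIN6, 309 to 321 for islets, and from 404 upwards for liver and hepatocytes.

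ACREB carries part of the CREB protein, and the labels do not say whether a Creb1 probe set detects it, so Creb1 checks no label here. In MIN6 cells 1 of the 3 Creb1 probe sets read 6349 and 5421 in the ACREB arrays against 94.8 to 118 in the 4 other arrays. Its change was 5.73 ± 0.14 on the log2 scale (limma adjusted p = 1.22e-06). The other 2 Creb1 probe sets showed no such rise. In HEK293T cells the 4 CREB1 probe sets read 105 to 147 in the control and forskolin arrays of that experiment, and none read above that range in an ACREB array, where the lowest value was 80.1.

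In human islets, forskolin raised the orphan nuclear receptor NR4A2 most, by 3.46 ± 0.06 on the log2 scale (11.0-fold, limma adjusted p = 5.77e-08), from a mean intensity of 316 to 3482. SIK1, a kinase that restrains CREB coactivators, rose by 2.88 ± 0.07. The zinc finger gene ZNF331 rose 5.65-fold. The kinase SGK1 rose by 1.89 on the log2 scale, the transcription factor KLF4 by 1.87, the small GTPase GEM by 1.75, CHAC1 by 1.69, ATF3 by 1.66, and the cytokine IL1A by 1.57. The MAP kinase phosphatase DUSP1 rose 2.82-fold. Of the other fixed genes, FOS rose by 1.36 ± 0.08, CREM by 0.83, NR4A1 by 0.63 (0.06 and 1.97 by its other probe sets, neither passing) and JUNB by 0.36, while the phosphodiesterase PDE4D had a change of 0.03 ± 0.06 (adjusted p = 0.821). NR4A3, FOSB and PER1 were not tested. The largest falls were the homeobox gene DLX2 (-1.35 ± 0.17), the acetyl-CoA carboxylase ACACB (-1.26 ± 0.30), IGKC (-1.20), MME (-1.13), TCP10L3 (-1.10) and the histone H2AX (-1.10). Most of these falls rest on 1 probe set: the other probe sets read 0.14 for DLX2, 0.10 to 0.23 for ACACB, 0.00 for MME, -0.01 to 0.11 for H2AX and -0.42 to 0.45 for IGKC, and none of them passed. Among the rises another IL1A probe set read -0.02, while the other NR4A2 probe sets read 3.40 and 4.06 and passed. In all, 257 genes rose and 374 fell of 8340 tested, and 35 of the 631 changed by 2-fold or more, 21 up and 14 down. The 2 forskolin arrays came from another chip lot than the 2 untreated arrays, so lot and treatment cannot be told apart within the islets. Without the intensity filter the calls of 25 of the 49 named genes that passed ended, among them DLX2 (adjusted p = 0.148), ACACB (0.296), IGKC (0.109), MME (0.0752), H2AX (0.185), CHAC1, CREM (0.0708), NR4A1 (0.0752) and JUNB (0.123) and, of the genes named below, SLC2A3, HERPUD1, DDIT3, IL6, CDKN1A, TGIF1, PCK1, IRS2, TRIB1 and ATF2. Without the trend 8 of the 49 ended, among them ACACB (adjusted p = 0.0997) and JUNB (0.0523). The count was 66 without the filter (51 up and 15 down) and 261 without the trend (119 up and 142 down). It was 247 without untreated replicate 1, 234 without untreated replicate 2, 2104 without forskolin replicate 1 and 1321 without forskolin replicate 2, and quantile normalization split it as 323 up and 313 down and median centring as 333 and 323.

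The list of classic CREB targets moved most in islets: 17 of 25 tested genes rose and 2 fell (18 and 2 adjusted over the list alone), with a median change of 0.70 (camera adjusted p = 4.19e-23, and adjusted p = 0.318 with an estimated correlation). EGR1 and VGF were its falling members. Of 27 immediate early genes 15 rose and 3 fell (17 and 5 adjusted over the list alone; adjusted p = 3.69e-12, and 0.318 with an estimated correlation). Of 21 glycolysis and hypoxia genes 10 rose and 0 fell in limma's test (12 and 0 adjusted over the list alone), among them the vasodilator ADM (1.10), the glucose transporter SLC2A3 (1.27), the mTOR inhibitor DDIT4 (1.38) and PFKFB3 (0.69). That list had an adjusted p of 1.69e-13, and 0.318 with an estimated correlation. Of 23 genes of the ER stress and amino acid response 6 rose and 1 fell, including HERPUD1 (0.42) and DDIT3 (0.59), with 7 and 1 adjusted over the list alone (adjusted p = 1.56e-04, and 0.376 with an estimated correlation). Of 19 inflammatory genes 6 rose and 1 fell, both over all genes and adjusted over the list alone, with IL6 at 0.77, LIF at 0.50 and the chemokine CCL2 at -0.49 (adjusted p = 1.97e-04, and 0.318 with an estimated correlation). Of 17 growth arrest genes 5 rose, led by GADD45B (1.01), CCNG2 (0.72) and CDKN1A (0.38), with 6 up and 1 down adjusted over the list alone (adjusted p = 1.65e-04, and 0.376 with an estimated correlation).

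Beta cell genes went the other way in the islets: 6 of 20 fell and 0 rose in limma's test, or 10 and 0 adjusted over the list alone (adjusted p = 0.00153, and 0.497 with an estimated correlation). The transcription factors ISL1 (-0.63 ± 0.06) and PAX6 (-0.27) and the secretory granule genes VGF (-0.28) and SCG2 (-0.18) were among them. All 4 calls ended without the filter (adjusted p = 0.0507 for ISL1 and 0.128 to 0.169 for the others), those of PAX6 (0.0873), VGF (0.0864) and SCG2 (0.162) without the trend, and that of SCG2 with centring (0.0901). Of 7 markers of the other islet endocrine cells 1 fell, HHEX, also adjusted over the list alone, and the list had a median of -0.08 (adjusted p = 0.0964, 0.519 with an estimated correlation and 0.00656 with quantile normalization). Of 16 genes of the TGF beta, ID and Wnt regulator list, which also holds Notch genes, 6 rose and 1 fell (6 and 4 adjusted over the list alone), with TGIF1 at 0.89, HES1 at 0.86 and INHBA at 0.63 (adjusted p = 0.00248, and 0.438 with an estimated correlation). Other probe sets, none passing, read -0.18 and 0.69 for HES1 and 0.14 for INHBA. Of 18 gluconeogenesis genes 4 rose and 1 fell (4 and 2 adjusted over the list alone): G6PC1, PCK1 (0.70), IRS2 (0.70) and CEBPB (1.05) rose and TRIB1 (-0.50) fell. Its adjusted p was 0.0168, 0.376 with an estimated correlation and 0.099 without the filter. The clock list passed with 2 rising genes of 17, BHLHE40 (0.95) and NFIL3 (0.91), both also adjusted over the list alone (adjusted p = 0.00889, and 0.519 with an estimated correlation). The list of CREB factors and coactivators, which also holds CEBP genes, passed with 3 rising and 2 falling genes of 12. Adjusted over the list alone 4 rose and 2 fell. CEBPD stood at 0.58 and ATF2 at -0.27, and the list had a camera adjusted p of 0.0156, and 0.376 with an estimated correlation. The ATF2 call also ended with quantile normalization (adjusted p = 0.0547), with centring (0.0513) and without the trend (0.0691). Acinar, duct, stroma, endothelial and immune markers had medians between -0.08 and 0.02, with members on both sides of 0 in each list.

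**Figure D1:**
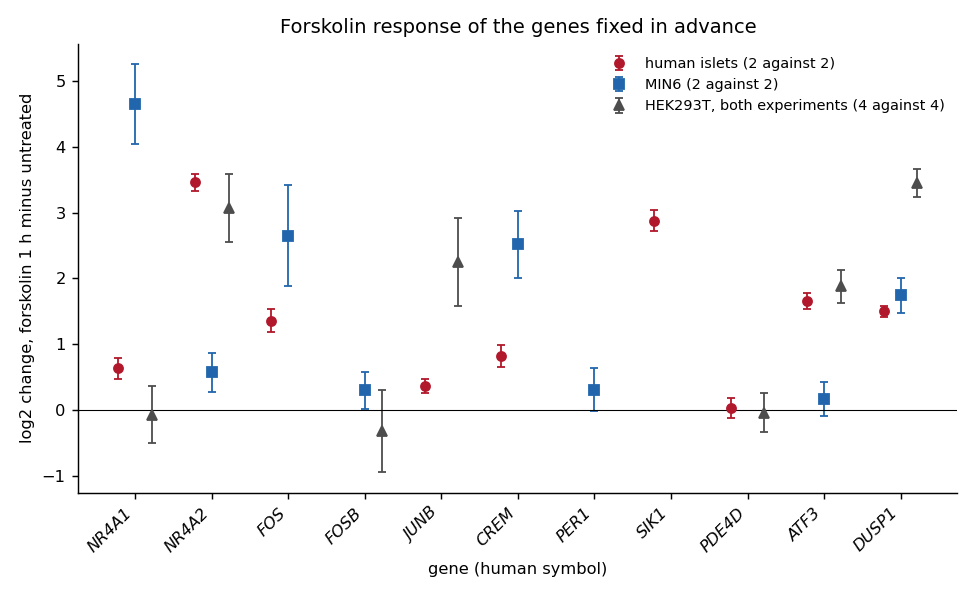
Log2 change after 1 h of forskolin (y axis) of the fixed CREB-responsive genes (x axis) in human islets (2 arrays against 2), MIN6 cells (2 against 2) and HEK293T cells (4 against 4). Points are limma estimates, bars are 95% confidence intervals, and a gene with no point was not tested there; NR4A2 stands at 3.46 in islets and 3.07 in HEK293T cells, and NR4A1 at 4.65 in MIN6 cells. Each gene is shown by 1 probe set; others read higher for NR4A2 and ATF3 in MIN6 cells, for DUSP1 (2.54) and NR4A1 (1.97) in islets and for NR4A1 in HEK293T cells (0.88 and 1.29).

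In MIN6 cells carrying the GFP virus, forskolin raised the nuclear receptor Nr4a1 by 4.65 ± 0.26 (25.1-fold, limma adjusted p = 4.37e-04), from an intensity of 115 to 2895. Cebpd rose by 3.72 ± 0.21, Fos by 2.65, Klf4 by 2.63, Crem by 2.52, the antiproliferative gene Tob1 by 2.16, Egr1 by 2.09, the polyamine enzyme Odc1 by 2.06, Tgif1 by 2.01, the insulin receptor substrate Irs2 by 1.91 and Dusp1 by 1.74. Nr4a2 depended on the probe set: the brighter one had a change of 0.57 (adjusted p = 0.0972), and the other, at the floor in the control arrays, rose by at least 3.76 (limma adjusted p = 0.0114). The brightest Atf3 probe set had a change of 0.16 and did not pass. The other 2 had 2.34 (limma adjusted p = 0.0619) and 1.23 (limma adjusted p = 0.051). These 2 were judged over all probe sets without the filter, a stricter test than that of the brightest one. Fosb (0.30) and Per1 (0.31) did not pass. Nr4a3, Junb, Sik1 and Pde4d were not tested. The 5 falls were Gng11 (-2.23 ± 0.32), the linker histone H1f10 (-1.22), the receptor Adgrg1 (-1.01), the beta cell transcription factor Pdx1 (-0.91) and Cd80 (-0.87). Another Cd80 probe set read 0.05 and did not pass. In all, 51 genes rose and 5 fell of 5666 tested. The 56 became 13 without the filter, 8 of them among the 56, where the calls of 19 of the 24 named genes ended, among them Nr4a1 (adjusted p = 0.0527), Fos, Klf4, Crem and the 5 falls. With only the compared arrays in the fit 26 rose and 0 fell by limma's test, and 12 of the 24 calls ended, among them the 5 falls (adjusted p = 0.0557 to 0.095), Fos, Tob1, Odc1, Cebpb (0.088), Foxa2, Nfkb2 and Relb. Without control replicate 1 there were 564, without forskolin replicate 1 there were 16 and without forskolin replicate 2 there were 7.

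In the same MIN6 comparison 8 of 22 classic CREB targets rose and 0 fell (11 and 0 adjusted over the list alone), with a camera adjusted p of 2.41e-08, and 0.372 with an estimated correlation. Of 19 immediate early genes 5 rose, including Ier2 (1.14), and 6 did so adjusted over the list alone (adjusted p = 4.42e-07, and 0.372 with an estimated correlation). Of 9 genes of the list of CREB factors and coactivators, which also holds Cebp genes, 3 rose, Crem, Cebpd and Cebpb (0.89). Adjusted over the list alone 4 rose, and the list had a camera adjusted p of 4.44e-05, and 0.372 with an estimated correlation. Of 20 ER stress genes 2 rose, the chaperone Dnajb9 (1.39) and Ddit4 (0.88), and 6 adjusted over the list alone (adjusted p = 0.00182, and 0.488 with an estimated correlation). Of 11 inflammatory genes Cebpd, Nfkb2 (0.91) and Relb (0.87) rose, and 4 adjusted over the list alone (adjusted p = 0.00482, 0.372 with an estimated correlation and 0.058 without the filter). Another Relb probe set read 0.18 and did not pass. Of 11 growth arrest genes Gadd45a rose (1.11), and adjusted over the list alone 4 rose and 1 fell (adjusted p = 0.037, 0.395 with an estimated correlation and 0.133 without the filter). The beta cell list passed narrowly with 1 rise, Foxa2 (0.75), and 1 fall, Pdx1, or 6 and 1 adjusted over the list alone (adjusted p = 0.0441, and 0.522 with an estimated correlation). Of 20 oxidative phosphorylation genes none passed singly in limma's test, also adjusted over the list alone, and the list had a median of 0.22 (adjusted p = 0.0441, and 0.488 with an estimated correlation). With quantile normalization the adjusted p was 0.088 for the beta cell list and 0.082 for oxidative phosphorylation, and the gene calls of Tob1 (0.0695), Cebpb (0.0575), Foxa2 (0.0549) and Relb (0.0761) ended. Of the genes in this paragraph Cebpb, Foxa2, Dnajb9, Nfkb2, Relb and Gadd45a also lost their calls without the filter.

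ACREB lowered 3 genes in forskolin-treated MIN6 cells relative to the GFP virus, namely Cebpd (-2.25 ± 0.21, limma adjusted p = 0.0112), beta-2-microglobulin B2m (-1.38 ± 0.12) and Irs2 (-1.06 ± 0.12). Phlda1 rose 2.63-fold, from an intensity of 150 to 395, and the Creb1 probe set described above also rose. Nr4a1 (-1.62, adjusted p = 0.124), Crem (-1.29, adjusted p = 0.131) and Dusp1 (-0.75, adjusted p = 0.0981) did not pass, nor did Fos (-0.80), Per1 (-0.48), Atf3 (-0.46) or Fosb (-0.13). The brighter Nr4a2 probe set (-0.46) did not pass either, while the other fell (-2.41 ± 0.10, limma adjusted p = 0.0336). Of 22 classic CREB targets 1 fell, and 8 fell adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.0106, 0.761 with an estimated correlation and 0.067 without the filter). Relative to control cells without forskolin, cells with ACREB and forskolin still had higher Nr4a1 (3.03), Cebpd (1.47), Dusp1 (1.00) and Irs2 (0.85), and Crem had a change of 1.23 (adjusted p = 0.103). The labels describe no ACREB cells without forskolin, so an effect of ACREB on basal expression was not separated. The 5 changed genes of 5665 tested became 11 with all probe sets (4 up and 7 down) and 54 with only the compared arrays in the fit (7 up and 47 down). Without the filter 4 genes changed, 1 of them among the 5, and the adjusted p was 0.21 for Cebpd, 0.0823 for B2m, 0.128 for Irs2 and 0.265 for Phlda1. There were 5 without GFP forskolin replicate 1 and 2 without GFP forskolin replicate 2, each with 1 of the original 5, and 1 without ACREB replicate 1 and 2 without ACREB replicate 2, with 0 of them by limma's test.

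Over 134 genes chosen because they rose in islets or HEK293T cells, the median ACREB effect in MIN6 cells was -0.13, against -0.06 over all genes. Of these genes 87 were lower with ACREB, and 2 passed limma's test as lower and 0 as higher (13 and 0 adjusted over the list alone). The median lay at the 0.03 percentile of random lists (camera p = 0.0282, and p = 0.392 with an estimated correlation). The same genes had a median of 0.24 for forskolin against control and 0.16 for ACREB with forskolin against control. Over the genes that passed the threshold in either source the median was -0.11 and without the filter it was -0.09, and camera's call ended in both. With quantile normalization the median was -0.04 over the 172 genes then chosen, against 0.01 over all genes, and the call held. The call ended without GFP forskolin replicate 2 (-0.09) and without ACREB replicate 1 (-0.15). Among the 51 genes that rose in MIN6 cells themselves, 44 were lower with ACREB, with a median of -0.53. These share the forskolin arrays with the comparison, so choosing them for a high forskolin value can itself lower the ACREB difference. Simulated unchanged ACREB effects gave a median of -0.01 over 100 draws (lowest -0.07). The simulation took the observed rises as true and left all other genes unchanged, so it cannot measure that bias in full.

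**Figure D2:**
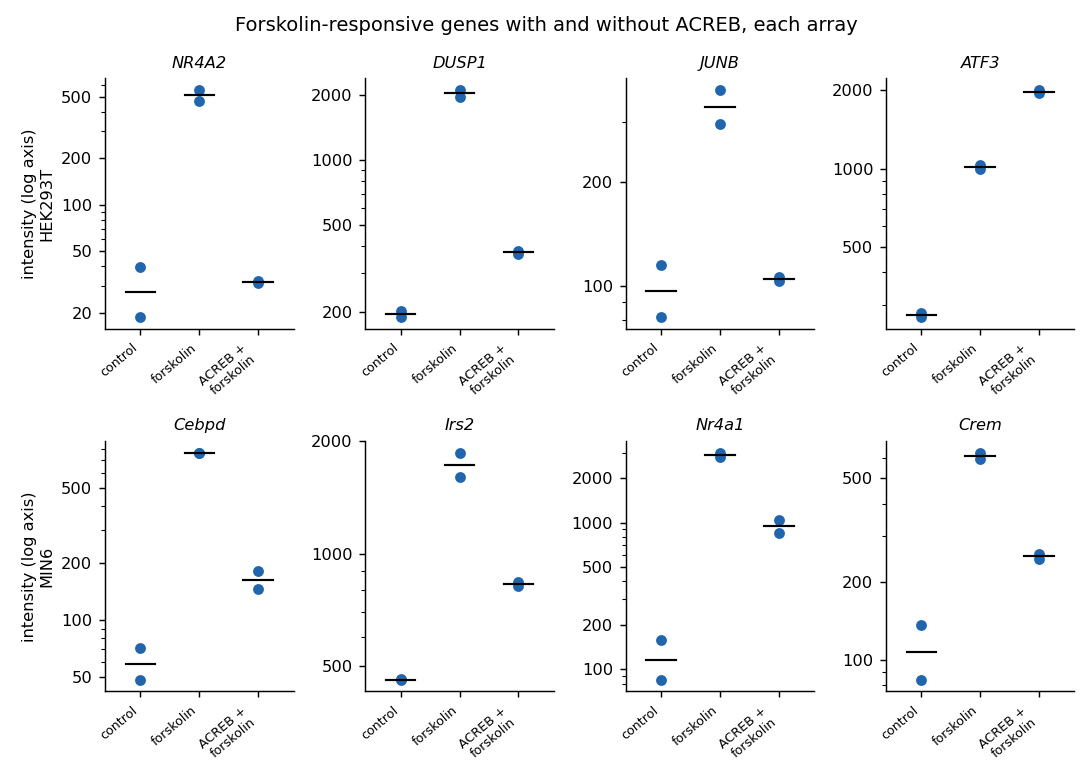
Deposited intensity (y axis, log scale) of 4 genes in HEK293T cells (top) and 4 in MIN6 cells (bottom) in control, forskolin and ACREB with forskolin arrays (x axis). Each point is 1 array and each bar a geometric mean of 2; in HEK293T cells DUSP1 moved from 194 to 2037 with forskolin and stood at 375 with ACREB, and in MIN6 cells Cebpd moved from 58.6 to 771 and stood at 162.

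In the HEK293T experiment with ACREB, forskolin raised NR4A2 by 4.03 ± 0.26 (16.4-fold, limma adjusted p = 9.9e-05), from an intensity of 31.2, close to the floor of 24.5. DUSP1 rose by 3.39 ± 0.11, ATF3 by 1.89 ± 0.09, JUNB by 1.77 ± 0.20 and the early gene IER2 by 1.30 ± 0.16. The monooxygenase CYP4B1 fell (-2.78 ± 0.36). CREM (-0.31 ± 0.21), NR4A1 (0.09) and PDE4D (0.05) did not pass, nor did the other 2 NR4A1 probe sets (0.97 and 0.87), and NR4A3, FOS, FOSB, PER1 and SIK1 were not tested. Of 20 classic CREB targets 4 rose (7 adjusted over the list alone; camera adjusted p = 5.44e-11, and 0.154 with an estimated correlation), and of 21 immediate early genes 4 rose (6 adjusted over the list alone; adjusted p = 9.61e-11, and 0.154 with an estimated correlation). The list of TGF beta, ID and Wnt regulators passed (adjusted p = 1.7e-05, and 0.169 with an estimated correlation), although none of its 14 genes passed over all genes. Adjusted over the list alone 3 rose, ID1 (0.72), ID4 (0.52) and ID2 (0.41). The 6 changed genes of 8282 tested became 3 without the filter and 3 without the trend. The calls of JUNB, IER2 and CYP4B1 ended without the filter (adjusted p = 0.537, 0.537 and 0.561) and without the trend (0.067, 0.131 and 0.194), that of NR4A2 without the filter (0.181) and that of JUNB with all HEK293T arrays in the fit (0.311). There were 3 without forskolin replicate 1 and 47 without forskolin replicate 2.

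With ACREB the forskolin-induced genes of HEK293T cells were lower: NR4A2 fell (-4.02 ± 0.26, limma adjusted p = 3.23e-05), as did DUSP1 (-2.44 ± 0.11) and JUNB (-1.65 ± 0.20). ATF3 instead rose by a further 0.96 ± 0.09. Relative to vector cells without forskolin, NR4A2 then stood at 0.02, JUNB at 0.12, IER2 at 0.15, DUSP1 at 0.95 and ATF3 at 2.86. In that comparison 726 genes rose and 803 fell by limma's test, against the 6 changed by forskolin alone. The labels describe no HEK293T cells with ACREB and without forskolin, so an effect of ACREB on basal expression was not separated. The largest rises with ACREB were the pseudokinase TRIB3 (3.26 ± 0.17), CYP4B1 (3.24), SH3BGR (3.12), NIBAN1 (2.99), the RNA-binding protein LARP6 (2.35), the uridine phosphorylase UPP1 (2.34), SH3BP1 (2.25), the cystathionine lyase CTH (2.13), IFT74 (2.08) and CADM3-AS1 (2.06). CYP4B1 had changed by -2.78 with forskolin in the arrays used as reference here, so its rise is measured from that low value. After NR4A2, the largest falls were the RNA-editing enzyme ADARB1 (-2.83), the chemokine receptor ACKR1 (-2.53), DUSP1, the isoprenoid enzyme IDI1 (-2.43) and GAS1 (-1.96). Another IDI1 probe set also fell (-2.41), but another GAS1 probe set read 1.05 (adjusted p = 0.139) and the other 2 of ADARB1 read -0.43 and -0.06, none passing, and with all HEK293T arrays in the fit ADARB1 stood at -0.55 (adjusted p = 0.291). Without the filter the ACKR1 call ended (adjusted p = 0.0836). CREM (0.30), NR4A1 (0.20) and PDE4D (0.27) did not pass, nor did the other 2 NR4A1 probe sets (-0.77 and -0.81). In all, 861 genes rose and 652 fell of 8277 tested, and 226 changed by 2-fold or more, 148 up and 78 down. Centring the arrays moved the median of all genes from 0.05 to -0.07 and the split to 504 up and 952 down, while quantile normalization gave 833 and 693. The count was 700 without the filter, 914 with all HEK293T arrays in the fit, 827 without forskolin replicate 1, 700 without ACREB replicate 1 and 577 without ACREB replicate 2.

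Of 18 cholesterol synthesis genes 10 fell and 0 rose in limma's test with ACREB in HEK293T cells (10 and 1 adjusted over the list alone), including IDI1, the squalene epoxidase SQLE (-1.59), INSIG1 (-1.13) and DHCR7 (-1.20). The list had a camera adjusted p of 2.86e-07, and 0.193 with an estimated correlation. Of 13 heat shock genes 9 fell and 1, HSF1, rose, with the same counts adjusted over the list alone. Examples were the mitochondrial co-chaperone HSPE1 (-0.96), DNAJA1 (-0.97), HSP90AB1 (-1.13) and HSPH1 (-0.69), with an adjusted p of 1.69e-05, and 0.193 with an estimated correlation. The HSP90AB1 call ended without the filter (adjusted p = 0.089), and its other probe set read -1.22 (adjusted p = 0.125). Of 28 cell cycle genes 6 fell and 0 rose in limma's test (8 and 0 adjusted over the list alone), including RRM2 (-0.98), AURKA (-0.87), CCNB1 (-0.69) and CCNA2 (-0.54), with an adjusted p of 2.48e-04, and 0.48 with an estimated correlation. Another CCNA2 probe set read 0.02, and the call of CCNA2 ended without the filter (adjusted p = 0.0623) and with all HEK293T arrays in the fit (-0.10, adjusted p = 0.767). The classic CREB target list did not pass (adjusted p = 0.201): 2 genes rose and 7 fell, its median was 0.09 and its mean -0.35. The beta actin control probe sets had a mean log2 3' to 5' ratio of 1.45 in the ACREB arrays and 0.66 in the 4 other arrays of the experiment, a sign of RNA quality that moved with these groups, and for GAPDH the means were 1.23 and 0.83.

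Over 47 genes chosen for their rise at 1 h of the HEK293T time course, the median ACREB effect was -0.14, against 0.05 over all genes, at the 1.55 percentile of random lists (camera p = 7.33e-05, and p = 0.0445 with an estimated correlation). Of these genes 30 were lower with ACREB, and 18 passed limma's test as lower and 5 as higher (18 and 7 adjusted over the list alone). The median was -1.68 over the 5 tested genes that had passed the threshold at 1 h, a limit chosen after seeing the data, and -0.24 without ACREB replicate 2. Most of the list had barely risen in this experiment, with a median of 0.10 for forskolin against control and -0.10 for ACREB with forskolin against control. Among the 5 genes that rose with forskolin in the same experiment 4 were lower with ACREB, with a median of -1.65. Simulated unchanged ACREB effects gave -0.02 (lowest -0.21). That simulation took the observed rises as true, so it cannot measure in full the bias of choosing genes on shared arrays.

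In the HEK293T time course DUSP1 rose by 3.43 ± 0.17 at 1 h (limma adjusted p = 2.85e-05), NR4A2 by 2.41 ± 0.22, the membrane protein CD82 by 2.37 ± 0.28, the metalloprotease ADAMTS1 by 2.33 ± 0.18, the glycoprotein hormone alpha chain CGA by 1.90 ± 0.21 and ATF3 by 1.78 ± 0.19. NR4A2 was represented by another probe set than in the ACREB experiment. Without the filter the calls of NR4A2 (adjusted p = 0.302), CD82 (0.348), ADAMTS1 (0.0664), CGA (0.348) and ATF3 (0.244) ended. The CD82 call also ended with only the compared arrays in the fit (adjusted p = 0.148), and CD82 had a change of 0.05 with forskolin in the experiment with ACREB. CREM (-0.10), NR4A1 (-0.31), PDE4D (-0.22), FOSB (-0.25) and NR4A3 (-0.77) did not pass by their brightest probe sets. Dimmer probe sets read 0.64 and at least 2.42 (limma adjusted p = 0.115) for NR4A3 and 0.70 and 1.63 for NR4A1. For CREM they read 0.03 to 0.91. None of these passed in the fit of all probe sets without the filter, a stricter test than that of the brightest ones. FOS, JUNB, PER1 and SIK1 were not tested. Of 22 immediate early genes 2 rose over all genes and 9 adjusted over the list alone (camera adjusted p = 0.0192, and 0.655 with an estimated correlation), with IER2 at 1.03 and JUN at 0.92. Classic CREB targets did not pass (adjusted p = 0.162): 4 of 21 rose, 7 adjusted over the list alone, with a mean of 0.41 but a median of -0.10. The lists of cell cycle (adjusted p = 0.00444), oxidative phosphorylation (0.0162) and cholesterol synthesis genes (0.0477) had positive medians of 0.29, 0.19 and 0.24 with no gene passing over all genes. Adjusted over the list alone 1, 0 and 5 of these genes rose and 1 cholesterol gene fell by limma's test, and each list had an adjusted p of 0.655 with an estimated correlation. With quantile normalization the adjusted p was 0.118, 0.139 and 0.139. The 3' to 5' ratios, a sign of RNA quality, were higher in both 1 h arrays than in both 0 h arrays, with mean log2 ratios of 0.94 against 0.63 for GAPDH and 0.84 against 0.55 for beta actin. All 6 changed genes of 8225 tested rose, and 1 passed without the filter, 99 with all HEK293T arrays in the fit and 16 without 1 h replicate 2 (6 up and 10 down), while quantile normalization gave 6 up and 1 down.

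At 4 h of the time course CGA had risen by 4.54 ± 0.21 (23.2-fold, limma adjusted p = 1.5e-05) and the complement regulator CD55 by 1.87 ± 0.18 (adjusted p = 0.006), the 2 changed genes of 8225. The CD55 call ended without the filter (adjusted p = 0.179). The next rises by p did not pass (adjusted p = 0.21): CD82 (1.76), DUSP1 (1.02), the histone H2BC6 (1.14) and the hexokinase HK2 (1.04). Nor did the falls nearest to passing, MYO16 (-1.80), MTMR7 (-0.98), WWC3 (-0.95) and GPR157 (-0.99). NR4A2 had a change of 0.47, ATF3 0.53, CREM 0.17, NR4A1 0.03, PDE4D 0.12, FOSB -0.13 and NR4A3 -0.49, none passing. Dimmer probe sets, also not passing, read at least 2.48 for NR4A3 (adjusted p = 0.104), 1.74 for NR4A1 and 1.37 for CREM. The immediate early list passed (camera adjusted p = 0.0348, and 0.809 with an estimated correlation) with 0 of 23 genes passing over all genes in limma's test and 2 up and 1 down adjusted over the list alone. These were JUN (0.73), DUSP1 and DUSP4 (-1.03), and the median of 0.09 turned to -0.02 with the arrays as deposited. Of 18 ribosomal protein genes all had small positive changes, such as RPL3 (0.30), with none passing singly, also adjusted over the list alone (adjusted p = 0.0348, 0.809 with an estimated correlation and 0.776 with quantile normalization). There were 4 changed genes with only the compared arrays in the fit, 14 with all HEK293T arrays in the fit, 4 without 0 h replicate 1, 9 without 0 h replicate 2 and 11 without 4 h replicate 2 (3 up and 8 down). The difference between 4 h and 1 h passed for 4 genes of 8226, with CGA higher at 4 h and DUSP1, NR4A2 and ADAMTS1 lower. With the arrays as deposited, the median of all genes moved from 0.05 to -0.06 at 4 h and from -0.01 to -0.14 for 4 h against 1 h.

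**Figure D3:**
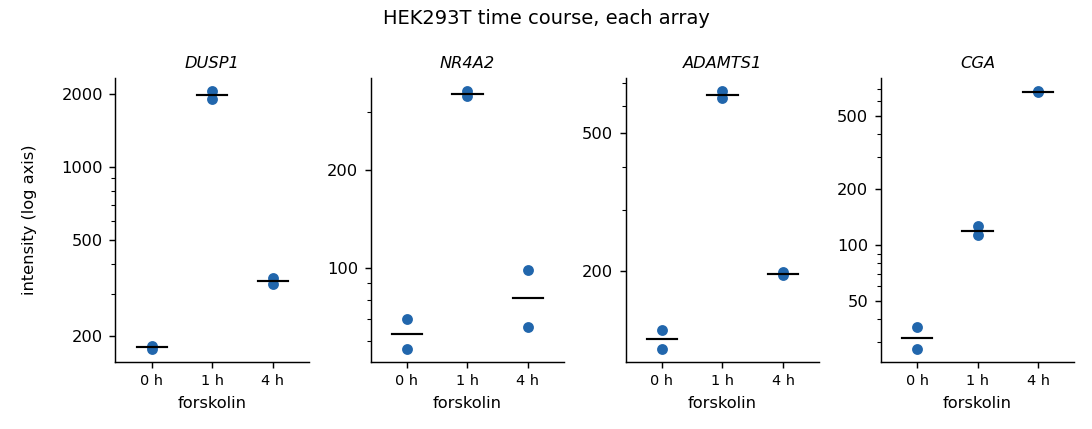
Deposited intensity (y axis, log scale) of 4 genes in HEK293T cells after 0 h, 1 h and 4 h of forskolin (x axis), with 1 point per array and a bar at the geometric mean of 2 arrays. After centring, DUSP1 was 3.43 above 0 h at 1 h and 1.02 at 4 h on the log2 scale, and CGA 1.90 and 4.54.

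Over the 8 arrays of both HEK293T experiments, 1 h of forskolin raised 9 of 8225 genes and lowered 0 by limma's test, with 832 genes at an unadjusted p under 0.05 in either direction. The 9 were DUSP1 (3.45 ± 0.10, limma adjusted p = 2.19e-09), NR4A2 (3.07 ± 0.24), JUNB (2.25 ± 0.31), ATF3 (1.88 ± 0.11), IER2 (1.21 ± 0.13), ID4 (0.86), JUN (0.85), ID1 (0.77) and MYC (0.61), the last with overlapping groups and named after its value was seen. NR4A1 (-0.07; 0.88 and 1.29 by its other probe sets), PDE4D (-0.04) and FOSB (-0.33) did not pass, and NR4A3, FOS, CREM, PER1 and SIK1 were not tested. Of 18 classic CREB targets 5 rose and of 21 immediate early genes 6, with 8 each adjusted over the list alone (camera adjusted p = 7.47e-07 and 2.65e-08, and 0.0767 for both with an estimated correlation). Of 14 TGF beta, ID and Wnt regulators ID1 and ID4 rose, and 6 adjusted over the list alone (adjusted p = 5.52e-04, 0.0767 with an estimated correlation and 0.114 without the filter). Both gene calls ended without the filter (adjusted p = 0.239), with quantile normalization (0.0885 and 0.112), without the trend (0.0742), with the replicate block (0.123 and 0.128), with the arrays as deposited (0.0657 and 0.083) and without the experiment as a block. The JUNB call ended without the filter (adjusted p = 0.457), with quantile normalization (0.0984), without control replicate 2 (0.06) and without the experiment as a block. The cell cycle list (median 0.17, adjusted p = 0.00465, and 0.607 with an estimated correlation) and the oxidative phosphorylation list (0.16, adjusted p = 0.00527, and 0.523 with an estimated correlation) had no gene passing, also adjusted over the list alone, and an adjusted p of 0.203 and 0.459 with quantile normalization. The effect of forskolin differed between the experiments for 0 of 8218 genes by limma's interaction test, with 966 at an unadjusted p under 0.05 where 410.9 would be expected by chance. Without the experiment as a block 1 gene passed.

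Genes raised by 1 h of forskolin were shared more often than independent lists would be in 5 of the 6 pairs of cell types. Islets and MIN6 cells shared 19 risers of 3476 genes tested in both, where 1.44 would be expected (odds ratio 27.8, Fisher's exact test, adjusted p = 4.28e-17). Among them were CREM, DUSP1, FOS, GEM, IRS2, KLF4, NR4A1, CEBPB, CEBPD, TGIF1 and TOB1. Islets shared 7 with hepatocytes at 2-fold (CREM, EFNA1, KLF4, MAFF, NFIL3, NR4A1 and PCK1; adjusted p = 1.38e-06) and 5 with HEK293T cells (ATF3, DUSP1, JUNB, MYC and NR4A2; adjusted p = 4.06e-06). MIN6 cells shared CREM, KLF4 and NR4A1 with hepatocytes (adjusted p = 2.47e-04) and DUSP1 and IER2 with HEK293T cells (adjusted p = 0.00165). HEK293T cells and hepatocytes shared 0 by Fisher's exact test, where 0.0191 would be expected (adjusted p = 1). With 8 and 14 risers among the genes tested in both, this pair could hardly show an overlap. Over the 100 largest rises of each cell type, whether or not they passed, this pair also passed. CREM, DUSP1, KLF4 and NR4A1 rose in 3 cell types, 24 genes in exactly 2 and 0 in all 4. These counts use 1 probe set per gene. A gene not tested in a cell type, such as CREM in HEK293T cells, could not count there. By the other Nr4a2 probe set in MIN6 cells NR4A2 also rose in 3 cell types. Other Atf3 probe sets read 2.34 and 1.23 in MIN6 cells without passing. In the exact binomial test of directions, 94 of 122 islet risers were positive in MIN6 cells (77.0% against 60.8% of other genes, adjusted p = 0.0011). Of the MIN6 risers 32 of 41 were positive in islets (adjusted p = 3.78e-05), 30 of 34 in HEK293T cells and 28 of 44 in hepatocytes (adjusted p = 0.0361 each), and of the HEK293T risers 8 of 9 were positive in islets (exact binomial adjusted p = 0.0161). The other 7 of the 12 directions tested did not pass.

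Fasted liver was compared with refed liver with 1 array each, so these values describe 2 livers and have no replicate check. The insulin-like growth factor binding protein Igfbp1 was 24.6-fold higher in the fasted liver (168 against 4126), the metallothioneins Mt2 and Mt1 13.8-fold and 7.23-fold, Crls1 7.27-fold and the lipid regulator Lpin1 5.77-fold. Ankrd33, Zbtb16, the acute phase genes Lcn2 and Saa2, and Crisp2 (at least 5.50-fold) completed the 10 largest rises. The largest falls were Cyp4f13 (at least 93.1-fold lower), Cdk5rap2, Nrep, the retinoic acid hydroxylase Cyp26a1 (at least 7.79-fold), Tubb2a (at least 6.15-fold) and the feeding-induced Angptl8 (5.35-fold). Of 24 gluconeogenesis genes all 24 were higher in the fasted liver, against a median of 0.14 over all genes, with a median of 0.46 at the 100 percentile of random lists. Got1 was 2.58-fold higher and the glucose-6-phosphatase G6pc 2.33-fold, while Pck1 (1.38-fold), Tat (1.41-fold) and Ppargc1a (1.32-fold) were under 2-fold. All 24 fatty acid oxidation and ketogenesis genes were higher (percentile 99.88), with Angptl4 at 3.83-fold and Acot1 at 2.19-fold. Cholesterol synthesis genes had a median of -0.22 at the 0 percentile, with Sqle at -2.11, Fdps at -1.81, Idi1 at -1.69 and Hmgcs1 at -1.03 on the log2 scale. Lipogenesis and glycolysis genes lay at the 0.06 percentile, with Thrsp at -1.79, Srebf1 at -1.60 and Fasn at -1.50. Heat shock genes (0 percentile, Hsph1 at -1.51) and ER stress genes (0.01 percentile, Sdf2l1 at -1.52) were also low. In all, 76 genes were higher and 47 lower at 2-fold of 12909 measured. Quantile normalization moved the median of all genes from 0.14 to 0.01 and gave 59 higher and 60 lower, with 22 of the 24 gluconeogenesis genes and 21 of the 24 fatty acid genes above 0.

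The fixed CREB-responsive genes moved little in the liver: Junb was 2.18-fold and Dusp1 1.57-fold higher in the fasted sample, and Nr4a1 (1.21-fold), Sik1 (1.15-fold) and Atf3 (1.24-fold) were closer to equal. Per1 (1.32-fold), Fosb (1.28-fold), Fos (1.14-fold), Nr4a3 (1.12-fold), Nr4a2 (1.10-fold) and Pde4d (1.01-fold) were also under 2-fold higher, and Crem was 1.06-fold lower. Classic CREB targets as a list lay at the 98.65 percentile, immediate early genes at 99.25, with Ccn2 at 2.64-fold, and TGF beta, ID and Wnt regulators at 99.48, with no gene at 2-fold.

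**Figure D4:**
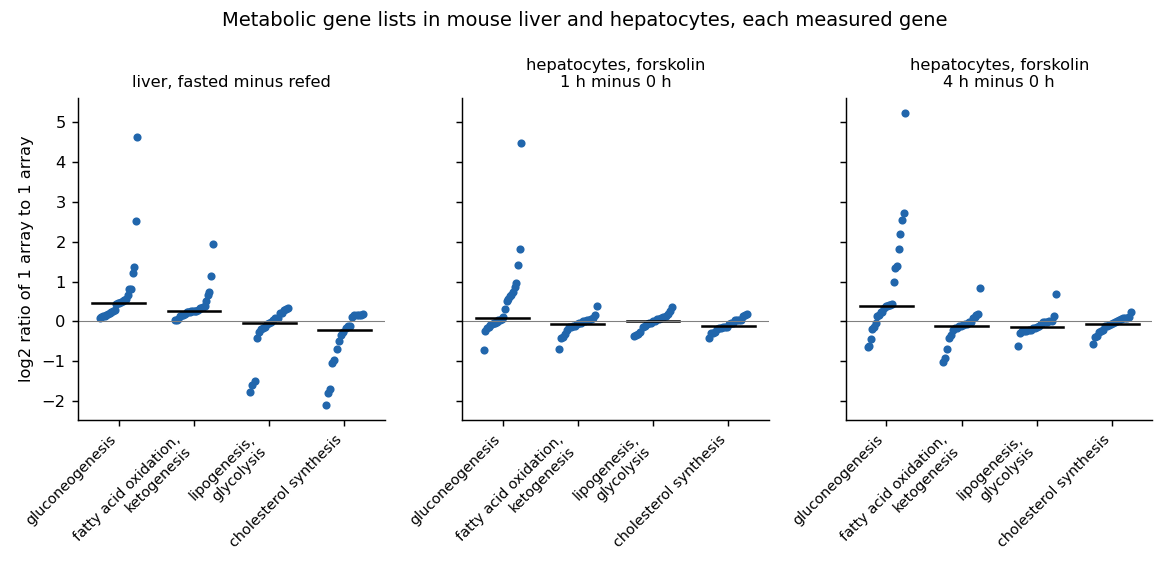
Log2 ratio of 1 array to 1 array (y axis) of each measured gene of 4 metabolic lists (x axis) in liver, fasted against refed, and in hepatocytes after 1 h or 4 h of forskolin against 0 h. Each point is a gene and each bar the list's median; all 24 gluconeogenesis genes lie above 0 in the liver (22 with quantile normalization), with a median of 0.46, and cholesterol synthesis genes have a median of -0.22 there.

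In primary hepatocytes, again with 1 array per time, the gluconeogenic enzyme Pck1 was 22.2-fold higher after 1 h of forskolin (126 against 2800). The ephrin Efna1 was at least 9.13-fold higher, Rasgef1b 7.08-fold, the inositol kinase Ipmk at least 4.90-fold, the transcription factor Nfil3 4.57-fold, Plk3 4.34-fold, Gadd45g 4.08-fold, Nr4a1 4.02-fold, Adamts1 3.91-fold and the cytokine signalling inhibitor Socs3 3.74-fold. Crem was 3.13-fold higher, the tyrosine aminotransferase Tat 3.55-fold and Got1 2.67-fold. The other fixed genes were under 2-fold, with Junb at 0.93 on the log2 scale, Sik1 0.91, Atf3 0.85, Dusp1 0.77 and Igfbp1 0.66. Fos stood at 0.62, Pde4d at 0.57, G6pc at 0.55, Nr4a2 at 0.40, Per1 at 0.28 and Nr4a3 at 0.17. Srebf1 (-0.04) and Ppargc1a (-0.20) were lower, and Fosb, at the floor after 1 h, was at least 1.25-fold lower. Gadd45a (-1.41), F3 (-1.28), Klf6 (-1.24), Heyl (-1.20), Cxxc4 (-1.17) and Tmed2 (-1.03) were the lowest on the log2 scale. Classic CREB targets lay at the 100 percentile of random lists, with 21 of 28 genes positive and 6 at 2-fold, the clock list at 99.91, TGF beta, ID and Wnt regulators at 99.67 and gluconeogenesis at 99.2. In all, 29 genes were higher and 7 lower at 2-fold of 12639, and 66 genes changed when all probe sets were used.

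After 4 h Pck1 was 38.0-fold higher in hepatocytes, Ipmk at least 10.1-fold, the amino acid transporter Slc7a2 7.53-fold, Crem 7.22-fold, Tat 6.66-fold, the ornithine transporter Slc25a15 5.84-fold, Got1 4.62-fold and G6pc 3.52-fold. Gluconeogenesis genes lay at the 100 percentile, with 18 of 24 positive and 7 at 2-fold, classic CREB targets at 99.4 and interferon-stimulated genes at 99.55, the last with no gene at 2-fold. Sik1 was 2.31-fold higher. Nr4a1 (1.48-fold), Fos (1.02-fold) and Nr4a2 (1.09-fold) were under 2-fold, as were Dusp1 (1.54-fold), Igfbp1 (1.31-fold), Ppargc1a (1.27-fold) and Pde4d (1.09-fold). Per1 (-0.03), Atf3 (-0.16), Nr4a3 (-0.18) and Srebf1 (-0.25) were slightly lower on the log2 scale. Fosb, at the floor after 4 h, was at least 1.25-fold lower. Phlda1 (-2.27), Ckm (-2.02), the matricellular protein Ccn2 (-2.01), Lrrn3 (-1.89), Cxcl2 (-1.89) and Phldb2 (-1.78) were the lowest on the log2 scale, and Junb stood at -1.25. In all, 55 genes were higher and 73 lower at 2-fold of 12589, quantile normalization turned this to 67 higher and 49 lower, and 218 genes changed when all probe sets were used.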

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

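The test of the ER stress list and the alternatives of the 4 h against 1 h contrast were chosen after the result was seen. The other tests here were set beforehand, except for a limit on single marker genes in the islets. Between 4 h and 1 h of forskolin in HEK293T cells, limma found differences of -2.41 for DUSP1 (adjusted p = 7.89e-04), 2.63 for CGA (0.00122), -1.94 for NR4A2 (0.0128) and -1.59 for ADAMTS1 (0.0128) on the log2 scale. In limma, 0 genes passed that test without 1 h replicate 1, 0 without 1 h replicate 2, 0 without the intensity filter and 1 without 4 h replicate 1. With all arrays 592 genes had an unadjusted p under 0.05.

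Of the 12 fixed CREB-responsive genes, 2 had arrays of 2 systems that parted in opposite directions by 1 probe set each, and these differences were not tested. Genes outside this set were not compared in this way. EGR1, for example, fell in islets and rose in MIN6 cells. The CREM values in HEK293T cells (-0.31 with forskolin, 0.30 with ACREB) and the ACREB effects on Crem and Atf3 in MIN6 cells did not pass limma's test, and the other 3 CREM probe sets read 0.07, -0.13 and -0.39 with forskolin in that experiment. The forskolin effect on CREM was higher by 1.13 in islets and by 2.82 in MIN6 cells than in the HEK293T experiment with ACREB. The ACREB effect was higher in HEK293T than in MIN6 cells by 1.59 for CREM and by 1.42 for ATF3. Probe sets that name no single gene also changed: 47 of 1654 in islets, 8 of 837 with forskolin and 2 of 837 with ACREB in MIN6 cells, 2 of 1646 with forskolin and 209 of 1646 with ACREB in HEK293T cells, 3 of 1789 at 4 h of the time course and 2 of 1698 in the pooled HEK293T arrays.

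ACREB changed 1513 genes in HEK293T cells and 5 in MIN6 cells, on different array types and with different delivery, and the difference was not tested. The 5 include the Creb1 probe set that rose in the ACREB arrays, which may read the delivered ACREB and so be no response to it. Scaling as the whole cause is argued against, since quantile normalization gave 1526 genes. RNA quality cannot be told apart from ACREB: the log2 3' to 5' ratio of beta actin was higher by 0.785 in the ACREB arrays, more than the range of 0.571 among the others, while the GAPDH difference of 0.396 was within its range of 0.663. A candidate explanation is a stress response of the ACREB cells, as the ER stress and amino acid response list had a median of 0.19 at the 99.63 percentile of random lists. Against a uniform rise, 8 of its genes rose and 6 fell, and camera gave an adjusted p of 0.201; the cell type and the extent of CREB inhibition stay open as untested biological explanations.

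In the islets 631 genes changed while chip lot and treatment coincided. A lot effect alone is argued against for the genes that rose and were also tested in MIN6 cells, which share no array with the islets. Of these 122 genes 77.0% were positive in MIN6 cells, against 60.8% of other genes (exact binomial p = 1.84e-04). That test treats genes read on the same arrays as independent, so its p may be too small. The share describes the genes as a set and does not tell which of them responded to forskolin. For the genes that fell, lot and forskolin cannot be told apart. Of the 137 also tested in MIN6 cells 38.7% were negative there, as were 38.7% of other genes (exact binomial p = 1). A changed share of acinar, duct, stroma, endothelial or immune cells cannot be told apart from forskolin. The farthest marker median was -0.0848, for immune cells. By the bound of 0.3 set beforehand on the medians, this explanation would have been argued against. Members went both ways in each list (-0.48 to 0.52 for stroma), and that bound did not allow for their spread. A limit on single members was therefore added to it, and the question is left open. Forskolin may account for part of the rises, as a hypothesis that the 77.0% bears on.

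The 2 HEK293T experiments had unlike profiles, with correlations of 0.652 to 0.823 between their arrays and 0.955 to 0.976 between replicates. A difference in 3' bias is argued against by a difference of the mean log2 ratio of only -0.324 for beta actin and -0.19 for GAPDH. Whether other cells lie behind one label cannot be told apart: the rank correlation over genes between the experiments exceeded that of the ACREB experiment with islets by 0.0812 (0.704 against 0.623), between the bounds set for either answer. Transfection in one experiment stays open, as does separate processing of the 2 experiments by the authors, since the dChIP normalization is not given in the sources used here, and no biological explanation was tested.

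Chance was not excluded for the count of genes in the pooled HEK293T arrays, as the test of splits could not decide it. Of the 35 splits of the 8 arrays into 4 and 4, 3 gave at least the 9 genes of the real split. These were the real split itself, the split that follows the experiments, and 1 other with 10 genes. With the first 2 always counted, the bound set beforehand could not be met. The remaining splits gave at most 3 genes. The highest other count was 5725, in the split that follows the experiments, which points to a structure of the samples, and in that split the experiment cannot be fitted as a block. The real split gave 9 genes with the experiment as a block and 1 without it.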

How the results depend on the processing

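Median centring or its omission, the crossed numbers, the lists limited to adjusted p and all alternatives of the 4 h against 1 h contrast were chosen after seeing the data, and the other alternatives before. Of 1554 checks of 129 named results (a gene in a comparison) that passed, 1337 kept direction and threshold, 214 lost the threshold (94 on leaving out a replicate, 64 without the filter, 8 with quantile normalization) and 3 turned; 57 of the 129 did neither in any check. Leaving out a replicate ended or turned 5 of 49 named calls in islets, 17 of 24 and 5 of 5 for forskolin and ACREB in MIN6 cells, 3 of 6 and 1 of 29 for the same in HEK293T cells, 4 of 6 at 1 h, 1 of 2 at 4 h and 3 of 8 pooled. The 3 turns came from another probe set representing the gene: H2AX in islets without untreated replicate 1 (0.084, main probe set -0.98; -1.36 without forskolin replicate 1), and Creb1 in MIN6 cells without ACREB replicate 1 (-0.23, main probe set 5.62) and ACREB replicate 2 (-0.14, main probe set 5.85; 5.83 without GFP forskolin replicate 2). Of the counts below, the cause of a move was not tested, except that the fits without the filter test more genes and those leaving out arrays use fewer. Where 1 array of a group was left out, the other is assumed to vary like the other groups.

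Without the filter, which adds genes held at the floor, the counts were 66 in islets, 13 in MIN6 and 3 in HEK293T cells with forskolin, 700 with ACREB in HEK293T cells, 1 at 1 h of the time course and 0 for 4 h against 1 h. Without the trend they were 261 in islets and 3 for forskolin in HEK293T cells. With only the compared arrays in the fit they were 26 and 54 for forskolin and ACREB in MIN6 cells, 4 at 4 h and 14 for 4 h against 1 h. With all HEK293T arrays in the fit they were 914 with ACREB, 99 at 1 h, 14 at 4 h and 19 for 4 h against 1 h. With all probe sets there were 11 for ACREB in MIN6 cells and 66 and 218 at 1 h and 4 h in hepatocytes. The pooled HEK293T arrays gave 1 without the experiment as a block. With an estimated correlation 0 of the 37 list calls remained, and camera with the preset correlation made all 37. The estimated form rests on few residual degrees of freedom, so this loss cannot tell whether correlation between genes made the calls. The median for ACREB in MIN6 cells was -0.093 without the filter (p = 0.331), -0.13 with an estimated correlation (p = 0.392) and -0.11 over genes at adjusted p under 0.05 (p = 0.0687).

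Leaving out each replicate gave 234 to 2104 genes in islets, 7 to 564 and 1 to 5 for forskolin and ACREB in MIN6 cells, 3 to 47 and 577 to 1174 for the same in HEK293T cells, 4 to 16 at 1 h, 2 to 11 at 4 h, 7 to 11 pooled and 0 to 6 for 4 h against 1 h. The MIN6 ACREB median ran from -0.148 to -0.083, and the HEK293T one from -0.24 to -0.13. The replicate numbers are only shared numbers, as deviations of same-numbered arrays correlated at 0.08 in islets and between -0.18 and 0.10 elsewhere. With the replicate block the counts were 1457 in islets, 14 at 1 h, 7 at 4 h and 12 for 4 h against 1 h, and the others moved by under 1.5 times. Camera's adjusted p was then 0.081 and 0.069 for the immediate early and ribosomal lists at 4 h, and 0.065 and 0.07 for the beta cell and oxidative phosphorylation lists in MIN6 cells, where centring gave 0.051 and 0.056. Crossing the numbers gave 4 genes for forskolin in HEK293T cells and 9 at 1 h. The floor at the 20th percentile left every count within 1.5 times. Genes near the floor, such as NR4A2 in untreated HEK293T cells, have the least signal over background and their changes are the least exact.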

Other observations

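The genes of the ER stress and amino acid response list named here were chosen after their values were seen, and the comparison with vector cells without forskolin was not among those set beforehand as a test of lists. With ACREB in HEK293T cells 8 genes of this list rose, among them DDIT3 (1.93), SLC7A11 (1.68), ASNS (1.14) and TRIB3 (3.26), and 6 fell, among them CALR (-0.88) and SDF2L1 (-0.85), by limma's test, or 10 and 7 adjusted over the list alone (camera adjusted p = 0.201, and 0.75 with an estimated correlation). No smaller list within it was tested. Relative to vector cells without forskolin, 9 of its 22 genes rose and 4 fell, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.0401, and adjusted p = 0.537 with an estimated correlation). In that comparison 9 of 19 glycolysis and hypoxia genes fell and 2 rose, with 9 and 3 adjusted over the list alone (adjusted p = 0.0191, and 0.436 with an estimated correlation), and 7 of 16 lipogenesis genes fell and 1 rose, with 9 and 2 adjusted over the list alone (adjusted p = 0.0191, and 0.436 with an estimated correlation). Cholesterol synthesis fell there too, 11 of 18 genes (13 down and 1 up adjusted over the list alone; adjusted p = 3.17e-07, and 0.229 with an estimated correlation).

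Between 4 h and 1 h of forskolin in HEK293T cells, ribosomal protein genes had a median of 0.16 (camera adjusted p = 0.00744, and 0.807 with an estimated correlation), and gluconeogenesis (-0.26, adjusted p = 0.00744) and TGF beta, ID and Wnt regulators (-0.26, adjusted p = 0.0128) were lower, both at an adjusted p of 0.58 with an estimated correlation. No gene of these lists passed limma's test over all genes, where 592 genes had an unadjusted p under 0.05, and adjusted over the list alone 0, 1 and 3 fell.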
